A study of Rattus norvegicus with 4 samples.

How the data were processed

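RNA was measured in left ventricle of male Sprague Dawley rats that had 5/6 nephrectomy, the surgical removal of most of the kidney mass, at 10 weeks of age. Per the labels, the rats ate a 0.4% Dyets chow and received a locked nucleic acid (LNA) oligonucleotide, either an inhibitor of miR-21-5p (anti-miR-21) or a scrambled control (anti-scr). An LNA is a short chemically stabilised strand that pairs with its target RNA. The doses were 1 mg/kg, given on 3 consecutive days in week 1 and again in week 4 after surgery, and tissue was taken in week 7. Each group held 2 libraries, and each library was made from pooled RNA of 2 to 3 rats, so the spread between libraries is a spread between pools. Per the labels, libraries were made with a stranded total RNA kit and read as pairs on an Illumina HiSeq instrument. Such a library measures messenger and long noncoding RNA, so the level of mature miR-21-5p was not analysed here.

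The authors' deposited FPKM values (fragments scaled by transcript length and by the number of mapped fragments) came as 1 value per locus and group, with no value per library, and the same table held a p-value and a q-value per locus. Per the submitters' processing notes, the tools were cutadapt, TopHat2 2.0.10, Cufflinks 2.0.10 and Cuffdiff, and the genome build was rn5; the annotation and the options were not given in the sources used here. In FPKM a change of a few very abundant transcripts shifts all other values, and reads shared between near-identical genes are divided by a model. A deposited count of reads per library, with the percent of bases at a quality of Q30 or above and the percent of reads mapped, came in a second table; whether a pair counts as 1 or 2 reads was not given in the sources used here. Depth was 48549754 and 53501488 reads in the anti-scr libraries and 54952098 and 47826514 in the anti-miR-21 libraries. Because the expression values are pooled, no interval per library could be computed, and the spread between pools could not be measured here. The deposited p-value accounts for it only as far as the authors' test did, with options that were not given.

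The expression table had 22861 loci. In 97 of them, all with several gene names, the cells stood shifted from their columns and were realigned. Folds were computed here as log2 of the anti-miR-21 FPKM over the anti-scr FPKM, because spreadsheet errors stood in place of some deposited folds. Beyond a tolerance of 0.002, the deposited fold differed from this ratio in 16 loci. Of the loci, 5676 carried no gene symbol, 257 carried several, and 25 names had been turned into dates. A locus with several genes has 1 value, so its genes cannot be separated. Where a gene had several loci, the locus with the highest mean FPKM was used. An FPKM of 0 can be a failed estimate: Sod1, a gene that every cell uses, was listed at 0 with anti-scr and at 900.4 with anti-miR-21. Such loci are therefore described only as listed at 0. The names anti-scr and anti-miR-21 are those of the column headers; an inhibitor leaves no target transcript in these data that could check them.

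A locus was called where the deposited q lay under 0.05. The planned model fit per library was replaced by this count, as the design fixed for pooled values. The 36 gene lists were fixed before the data were examined: 33 written by hand and 3 defined by gene symbol (ribosomal proteins, replication histones, small noncoding loci). For each list, the median log2 fold over loci with a mean FPKM of at least 1 in the 2 groups was set against 10000 random lists of the same size with the same spread over 20 bins of mean FPKM, drawn from 9960 named loci. A list is said to stand apart where its median lay outside the central 95% of the random lists. This percentile describes these libraries and is not a p-value, since genes are not replicates and members of a list can move together. Calls within a list were also counted after Benjamini-Hochberg adjustment of the deposited p-values over the list alone.

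Genes are named by a rule fixed before the data were examined. It takes a fixed panel (Ppara, Pdcd4, Spry1, Spry2, Reck, Timp3, Nppa, Nppb, Myh6, Myh7, Col1a1, Col3a1, Postn, Pdk4, Cpt1b and Vmp1), the 8 largest rises and the 8 largest falls among called loci with a symbol and an FPKM of at least 1 in both groups, leaving out immunoglobulin and RT1 loci and provisional names, and for each list up to 3 called members with the largest fold or, with none called, the 2 members with the highest FPKM. Some genes that the rule takes are not reported here. Genes outside this rule are marked as chosen after their values were seen. Gene density is the number of named loci whose midpoints lie within 500 kb on either side of a locus, from the deposited positions; it was added after the data were examined. Base composition was not analysed here.

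The alternatives set before the data were examined were other q thresholds, a fold minimum, an FPKM minimum with q recomputed, q recomputed over all tested loci, recentring on the median fold, FPKM minimums of 5 and 0.1, log2 of FPKM + 1, and the mean in place of the median. Random lists matched on gene density as well as expression, and folds with the median of their density decile removed, were added later. The list statistic was tested on simulated data: folds were drawn for 9877 loci in 50 simulations each, with 1000 random lists per simulation. Each locus was drawn independently of the others. In the real data neighbouring loci and members of a list can move together, so the rates below do not cover that case. The 29 fatty acid oxidation members with a position stood apart in 6% of simulations with no shift and in 92% with a shift of -0.2, and the 66 oxidative phosphorylation members in 2% and 100%. When the observed gene density trend was added, lists with no shift stood apart in 6% and 12% of simulations, or in 10% of both with density-matched random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.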

Results

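The transcriptome of the left ventricle was compared between 5/6 nephrectomised rats given anti-miR-21 and those given anti-scr, to ask what inhibition of miR-21-5p changes in the heart in chronic kidney disease. Each group had 2 libraries, each a pool of 2 to 3 rats. The libraries held between 47826514 and 54952098 reads, of which 94.0% to 94.4% mapped, and 96.0% to 96.2% of bases were at Q30 or above. FPKM values are the authors' group values, 1 per group, so the spread between pools can enter only through the deposited p and q. Folds are log2 of anti-miR-21 over anti-scr, and positions are on rn5.

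Genes of mitochondrial metabolism, ribosomal proteins and the sarcomere were among the falls with anti-miR-21, and genes of the extracellular matrix and of immune cells were among the rises. In the authors' deposited table, 105 of 12876 tested loci had a q under 0.05, of which 24 were higher and 81 were lower with anti-miR-21. Among called genes, the largest falls by the naming rule were Dohh, which encodes the enzyme that completes the hypusine modification of eIF5A, from 3.80 to 1.22 FPKM (log2 fold -1.64; chromosome 7, 11358018 to 11362832), and the ribosomal protein gene Rpl36, from 64.8 to 22.3 FPKM (-1.54; chromosome 9, 9438154 to 9438908). They were followed by the cytokine gene Mif (-1.50), the mitochondrial import chaperone gene Timm13 (-1.46), the complex I subunit gene Ndufs7 (-1.43), Ccdc124 (-1.37), the cardiac transcription factor gene Nkx2-5 (-1.29) and Fitm1 (-1.26), which acts in lipid droplet formation. The largest rises were the transcription factor gene Egr2, from 1.63 to 4.98 FPKM (1.61), and the secreted lectin genes Reg3b, from 32.6 to 91.5 FPKM (1.49), and Reg3g (1.48). Next came the sarcomere gene Mybphl (1.41), Slfn3 (1.38), the decoy receptor gene Tnfrsf11b (1.32), the matrix gene Postn (1.31) and the chemokine gene Cxcl13 (1.29). The deposited q of these 16 genes ranged from 0.0131 to 0.0491 in the authors' deposited table, where 0.0131 was the lowest q of any locus.

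**Figure D1:**
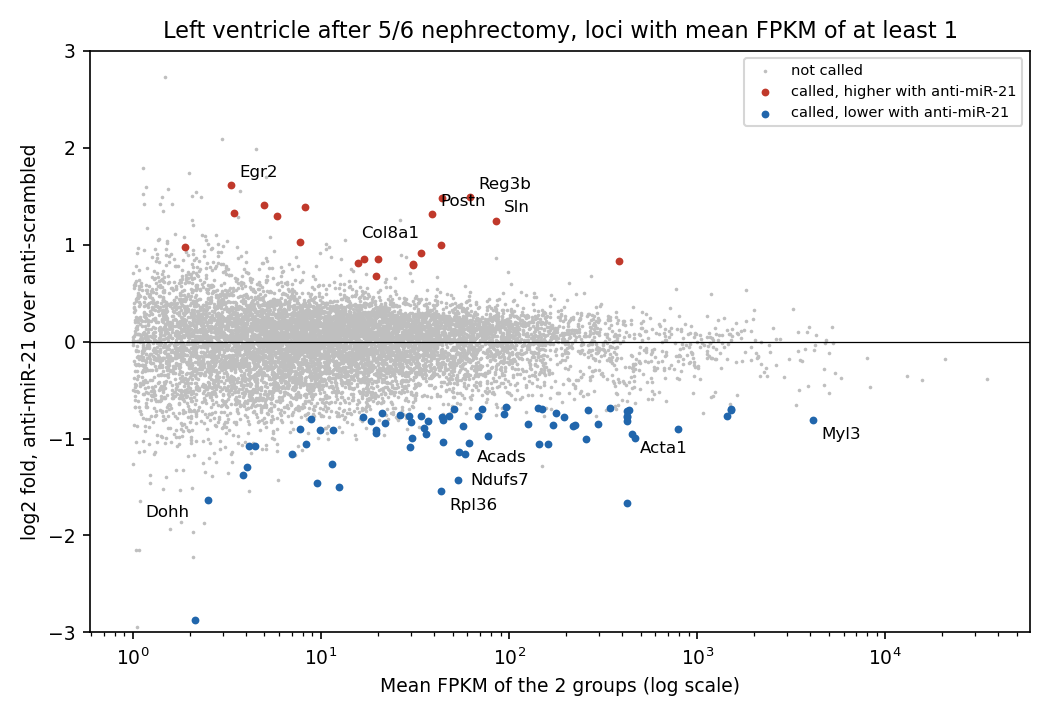
Each point is a named locus with a mean FPKM of at least 1. The x axis is the mean FPKM of the 2 groups on a log scale and the y axis the log2 fold of anti-miR-21 over anti-scr; 1 of 9960 loci lies outside the plotted range. Red points are the 20 called loci that were higher and blue points the 73 called loci that were lower with anti-miR-21 in the authors' deposited table.

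The first question was whether transcripts that miR-21-5p represses were higher when it was inhibited. None of the 38 measured members of the miR-21 target list was called in the authors' deposited table, and none passed when adjusted over the list alone. At an unadjusted p under 0.05, 2 members were higher and 0 lower in the authors' deposited table. Over all 12876 tested loci, 410 were higher and 787 lower at this threshold. The 2 members were Jag1 (log2 fold 0.53) and Rasgrp1 (0.66), chosen after their values were seen. By value alone, 25 members were higher and 13 lower. Their median log2 fold was 0.11, at percentile 97.06 of the random lists, just inside the range of -0.11 to 0.12 that holds the central 95% of them. The list stood apart with the mean in place of the median (percentile 99.41), at a mean FPKM of at least 0.1 (99.7) and with log2 of FPKM + 1 (97.73). It did not at a mean FPKM of at least 5 (85.49) or with random lists matched on gene density (94.41). Recentring shifts the list and its random lists alike, so its percentile of 97.34 differs from 97.06 only through the random draw. The percentile of 97.73 lay just outside the central 95% and can change sides with that draw. Matching on gene density raised the median of the random lists from 0.02 to 0.08, against 0.14 for the 37 members with a position. Among the panel genes on this list, the tumour suppressor gene Pdcd4 (32.8 and 38.8 FPKM with anti-scr and anti-miR-21) had a log2 fold of 0.24. Values for the protease inhibitor genes Reck and Timp3 were 0.20 and 0.50, and for the signalling inhibitors Spry1 and Spry2 they were -0.03 and 0.00. None of these 5 panel genes was called in the authors' deposited table, where their q ranged from 0.762 to 0.997. Vmp1, whose transcript overlaps the miR-21 gene, stood at 52.4 and 60.3 FPKM (q = 0.813 in the authors' deposited table). Tpm1 and Acat1, the most abundant members, had folds of -0.17 and -0.28.

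Genes of fatty acid oxidation were lower with anti-miR-21 as a group. Of 30 measured members, 27 were lower in value, 4 fell and 0 rose in the authors' deposited table, and 9 fell when adjusted over the list alone. The median log2 fold was -0.30, below all of the 10000 random lists (their central 95% ran from -0.16 to 0.08). Acads, a short-chain acyl-CoA dehydrogenase, fell from 82.1 to 39.8 FPKM (log2 fold -1.05; chromosome 12, 49049520 to 49059163). Slc27a1, a fatty acid transporter, fell from 12.9 to 6.85 FPKM (-0.91), and Mlycd, which removes the malonyl-CoA that blocks fatty acid entry into mitochondria, fell from 38.4 to 21.6 FPKM (-0.83). The fourth called member was the electron transfer gene Etfb (-0.71), chosen after its value was seen. Cpt1b, the muscle carnitine palmitoyltransferase, had 193.5 and 140.1 FPKM (-0.47) and was not called (q = 0.334 in the authors' deposited table).

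The transcription factor gene Ppara, a reported miR-21 target that drives many of these genes, did not differ by the deposited test. Its FPKM was 1.98 with anti-scr and 1.76 with anti-miR-21 (log2 fold -0.17; q = 0.974 in the authors' deposited table). Of 36 measured genes known to respond to PPAR-alpha, 28 were lower in value, 1 (Mlycd) fell in the authors' deposited table, and 2 fell when adjusted over the list alone. Their median log2 fold was -0.17, at percentile 0.77. Part of this list is shared with the fatty acid oxidation list. Pdk4, another responsive gene, had 366.6 and 368.3 FPKM (0.01). None of the 21 regulators of the PPAR and PGC-1 network was called in the authors' deposited table or when adjusted over the list alone, and their median was -0.02, at percentile 33.0; its most abundant members were Tfam (-0.02) and Prkaa2 (0.18).

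Respiratory chain and glycolytic genes were also lower as groups. Of 66 nuclear-encoded subunits of oxidative phosphorylation, 54 were lower in value, 8 fell and 0 rose in the authors' deposited table, 14 fell when adjusted over the list alone, and the median of -0.19 stood at percentile 0.09. Atp5f1 was split over several loci and is counted at its most abundant one, which was not called; another of its loci, chosen after its value was seen, was listed at 0 with anti-scr and at 15.9 FPKM with anti-miR-21 and was called in the authors' deposited table, so this gene is uncertain. Ndufs7 fell from 78.1 to 28.9 FPKM (chromosome 7, 12484486 to 12496122), the ATP synthase gene Atp5d from 218.2 to 104.7 FPKM (-1.06) and the complex III gene Uqcr11 from 539.4 to 305.6 FPKM (-0.82). In glycolysis, 17 of 22 members were lower in value and the median of -0.37 lay below all of the random lists; the muscle phosphoglycerate mutase gene Pgam2 (535.5 to 312.9 FPKM, -0.78) was the 1 called member in the authors' deposited table, and 3 fell when adjusted over the list alone. Of 19 genes of branched-chain amino acid and ketone use, 3 fell in the authors' deposited table: Bcat2 (-0.78), Bckdha (-0.77) and Pccb (-0.69). Adjusted over the list alone, 4 fell, and the median of -0.16 at percentile 2.64 did not stand apart. It did with the mean (percentile 0.76) and with density-matched lists (0.73). At a mean FPKM of at least 5 (2.28) or 0.1 (2.47) and with log2 of FPKM + 1 (2.36) it lay just past the limit of 2.5. At 0.1 the members and the median were those of the main setting, so only the random lists differed. Percentiles this near the limit can change sides with the random draw. Among 71 ribosomal protein genes, 56 were lower in value, 6 fell and 0 rose in the authors' deposited table, 10 fell when adjusted over the list alone, and the median was -0.18 (percentile 0.07); the largest called falls were Rpl36, Rps15 (-1.05) and Rps26 (-0.86). Ribosomal protein genes have many processed copies in the genome, so their single values are uncertain. The mitochondrially encoded genes were not analysed here.

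**Figure D2:**
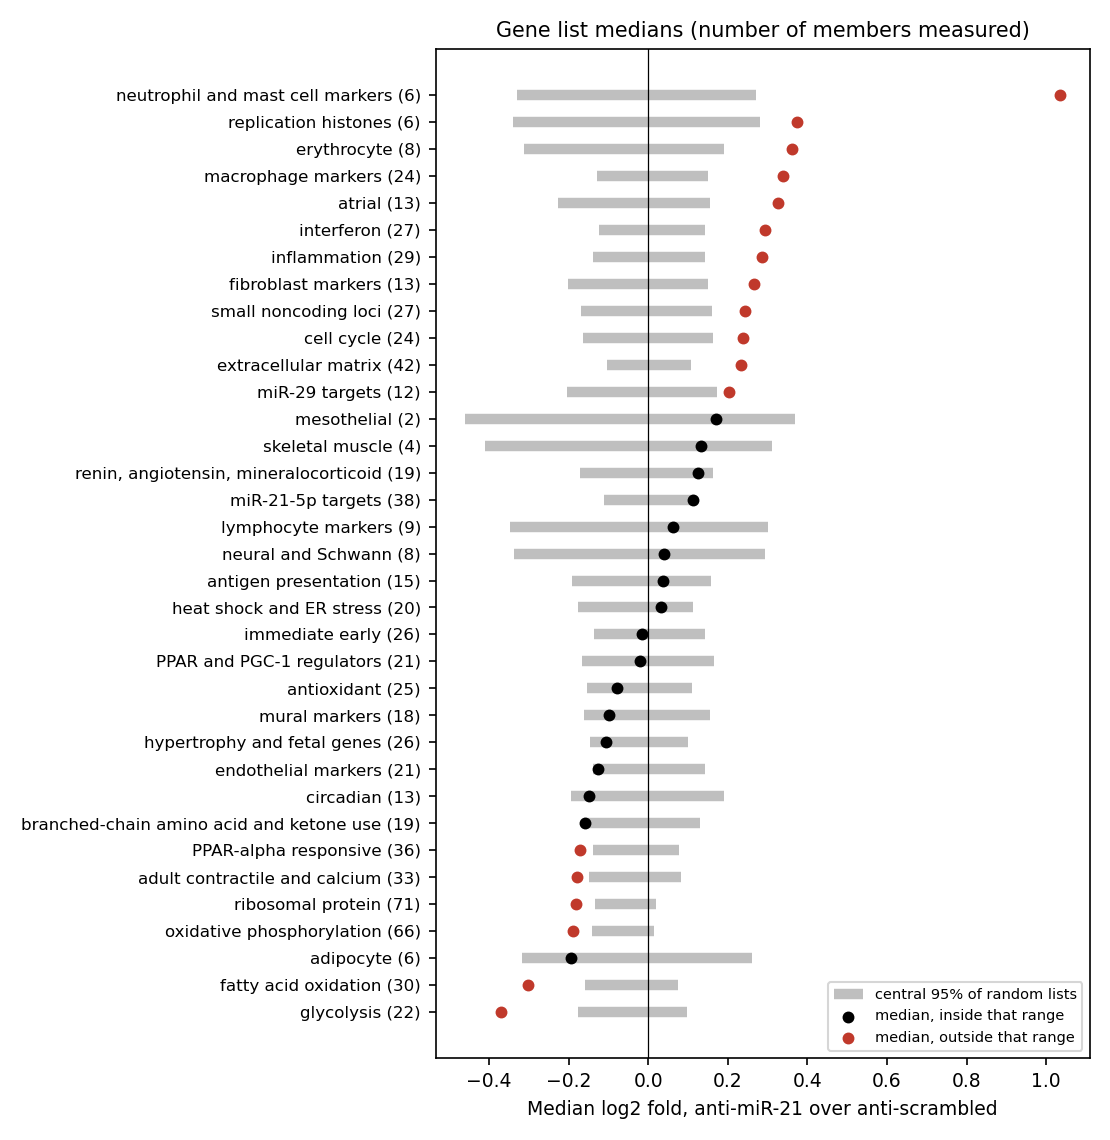
Each row is a gene list with its number of measured members. Dots are the median log2 fold of anti-miR-21 over anti-scr on the x axis, red where it lay outside the grey bar, which spans the central 95% of 10000 random lists matched on expression. Of 35 lists, 6 medians lay below and 12 above their bars. If the members of each list moved like randomly drawn loci, 1.75 would fall outside by chance. Members of a list can move together, so more can fall outside by chance.

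Contractile genes of the adult heart were lower as a group. Of 33 measured members, 20 were lower in value and the median was -0.18 (percentile 0.68). One member fell in the authors' deposited table, the ventricular myosin light chain gene Myl3, from 5253 to 3000 FPKM (-0.81), and another rose, Sln, which encodes the calcium pump inhibitor sarcolipin, from 50.3 to 119.3 FPKM (1.25). Adjusted over the list alone, 4 fell and 1 rose. With the mean in place of the median this list no longer stood apart. Sln is also on the atrial list, where 12 of 13 measured members were higher in value. Myh6 and Myh7, the adult and fetal myosin heavy chain genes, share 1 locus in the table and cannot be separated; that locus had 1336 and 804.3 FPKM (-0.73) and was not called (q = 0.242 in the authors' deposited table).

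The hypertrophy and fetal gene list moved in both directions, with 12 members higher and 14 lower in value, a median of -0.11 and percentile 8.14. With random lists matched on gene density as well, the list stood apart as lower at percentile 1.75. Skeletal actin, Acta1, fell from 590.3 to 305.0 FPKM (-0.95) and filamin C, Flnc, from 36.8 to 21.6 FPKM (-0.77); these were the 2 called members in the authors' deposited table. Adjusted over the list alone, 6 fell and 1 rose. The natriuretic peptide genes, standard markers of cardiac load, were not called in the authors' deposited table: Nppa had 1492 and 2165 FPKM (0.54, q = 0.209) and Nppb 670.8 and 625.5 FPKM (-0.10, q = 0.940).

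Extracellular matrix genes were higher as a group. Of 42 measured members, 30 were higher in value, 4 rose and 0 fell in the authors' deposited table, and 7 rose when adjusted over the list alone. The median of 0.23 lay above all of the random lists. Postn, a matrix protein made by activated fibroblasts, rose from 22.4 to 55.8 FPKM (chromosome 2, 163331223 to 163362445), the short-chain collagen gene Col8a1 from 14.3 to 25.7 FPKM (0.85) and Spp1, which encodes osteopontin, from 22.6 to 39.2 FPKM (0.79). The fourth called member was the fibrillin gene Fbn1 (15.2 to 24.2 FPKM, 0.67), also the 1 called member of the 12 measured genes of the miR-29 target list, which had a median of 0.20 (percentile 99.22); adjusted over the list alone, 2 of those 12 rose and 1 fell. The main fibrillar collagens were not called in the authors' deposited table: Col1a1 had 44.4 and 52.6 FPKM (0.24, q = 0.739) and Col3a1 627.0 and 915.5 FPKM (0.55, q = 0.213). Of 13 fibroblast markers, 11 were higher in value with a median of 0.27 (percentile 99.99), and none was called in the authors' deposited table; adjusted over the list alone, 1 rose and 1 fell. Its most abundant members were Dcn (0.27) and Gsn (-0.55).

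Markers of myeloid cells were higher as groups, and so were genes of red blood cells, while markers of vessel cells did not stand apart. Of 8 erythrocyte genes, 7 were higher in value with a median of 0.36 (percentile 99.95; Hba-a2 0.22, Hbb 0.12 at a locus shared with another gene), and none was called in the authors' deposited table or when adjusted over the list alone; at a mean FPKM of at least 5 the 6 genes left no longer stood apart (percentile 97.27). Of 24 macrophage markers, 20 were higher in value and the median of 0.34 lay above all of the random lists, although none was called in the authors' deposited table or when adjusted over the list alone; at an unadjusted p under 0.05, 6 were higher and 0 lower. The most abundant were Lyz2 (165.4 and 250.7 FPKM, 0.60) and Ctss (0.42). Of 6 neutrophil and mast cell markers, 5 were higher in value with a median of 1.03, above all of the random lists. S100a9, a neutrophil protein, rose from 29.2 to 58.1 FPKM (0.99) in the authors' deposited table, and 4 rose when adjusted over the list alone. Of 29 inflammation genes, 21 were higher in value (median 0.28, above all of the random lists), Spp1 alone was called in the authors' deposited table, and 6 rose when adjusted over the list alone. The 27 interferon-responsive genes had a median of 0.29, above all of the random lists, with none called in the authors' deposited table (5 higher and 1 lower at an unadjusted p under 0.05); Ifi27 (0.01) and Gbp2 (0.46) were the most abundant. None of the interferon-responsive genes passed when adjusted over the list alone. Medians of 9 lymphocyte markers (0.06, percentile 64.44; Cd4 0.29, Klrd1 0.12) and 15 antigen presentation genes (0.04, percentile 63.1; B2m 0.23, Cd74 -0.22) did not stand apart. Neither did those of 21 endothelial markers (-0.13, percentile 3.36; Aqp1 -0.18, Pecam1 -0.17) and 18 mural cell markers (-0.10, percentile 9.28; Rgs5 0.22, Abcc9 0.18). With random lists matched on gene density, the antigen presentation median stood apart as higher (percentile 99.84). None of these 4 lists had a called member in the authors' deposited table; adjusted over the list alone, 2 antigen presentation genes rose and 1 fell, and no member of the other 3 lists passed.

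Stress and growth responses were mixed. Of 26 immediate early genes, 13 were higher and 13 lower in value (median -0.02, percentile 30.53); in the authors' deposited table Egr2 and Egr1 (22.4 to 39.2 FPKM, 0.81) rose and Atf3 (25.9 to 13.4 FPKM, -0.94) fell. Adjusted over the list alone, 3 rose and 1 fell. Of the antioxidant genes with a fold, 1 of 25 was called in the authors' deposited table, the metallothionein gene Mt1a, which fell from 59.7 to 29.1 FPKM (-1.04), and the median was -0.08 (percentile 17.23); 1 fell when adjusted over the list alone. The lists of heat shock and endoplasmic reticulum stress (0.03, percentile 73.03; Cryab -0.45, Hspa8 -0.09), circadian genes (-0.15, percentile 5.5; Nr1d2 0.18, Bhlhe40 0.31) and renin, angiotensin and mineralocorticoid genes (0.13, percentile 92.66; Tsc22d3 0.21 at a locus on chromosome 3 that can be a copy of the gene, Klf9 0.23) did not stand apart and had no called member in the authors' deposited table. Adjusted over the list alone, 1 stress gene fell, 1 gene of the renin list rose and no circadian gene passed. The renin list stood apart at a mean FPKM of at least 5 (percentile 99.3) or 0.1 (97.89) and with the mean (97.6). Cell cycle genes did (24 genes, 0.24, percentile 99.84; Ccnd2 0.04, Pcna 0.22), as did 6 replication histone loci (0.37, percentile 99.52; Hist1h2bh 0.17, Hist1h4b 0.28), also with no called member in the authors' deposited table and none adjusted over the list alone. The histone median did not stand apart at a mean FPKM of at least 5 (3 loci, percentile 82.0) or 0.1 (10 loci, percentile 91.7).

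The size and direction of the fold followed gene position. Across 9877 named loci with a position, the log2 fold declined with the number of named loci within 500 kb on either side (Spearman's rho -0.43, Pearson's r -0.38); this is a correlation across genes, which are not independent replicates. The rank correlation was below 0 on all of the 21 chromosomes, from -0.66 to -0.02. The median log2 fold was 0.17 in the sparsest decile and -0.28 in the densest. In the densest decile 33 loci fell and 0 rose in the authors' deposited table, against 2 and 4 in the sparsest. The stretch of up to 2000 kb with the most called loci, picked after the values were seen, was on chromosome 7 from 11248739 to 13074382. There, where Dohh, Timm13, Ndufs7, Atp5d, Uqcr11 and Rps15 lie, 65 of 67 named loci were lower in value, 12 fell and 0 rose in the authors' deposited table. With random lists matched on density as well as expression, the fatty acid oxidation, PPAR-alpha, oxidative phosphorylation, glycolysis, ribosomal protein, contractile, extracellular matrix, fibroblast, macrophage, inflammation and interferon lists still stood apart in the same direction. The hypertrophy, antigen presentation and amino acid lists, which did not stand apart among lists matched on expression alone, did so with this matching, and the small noncoding list no longer did.

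**Figure D3:**
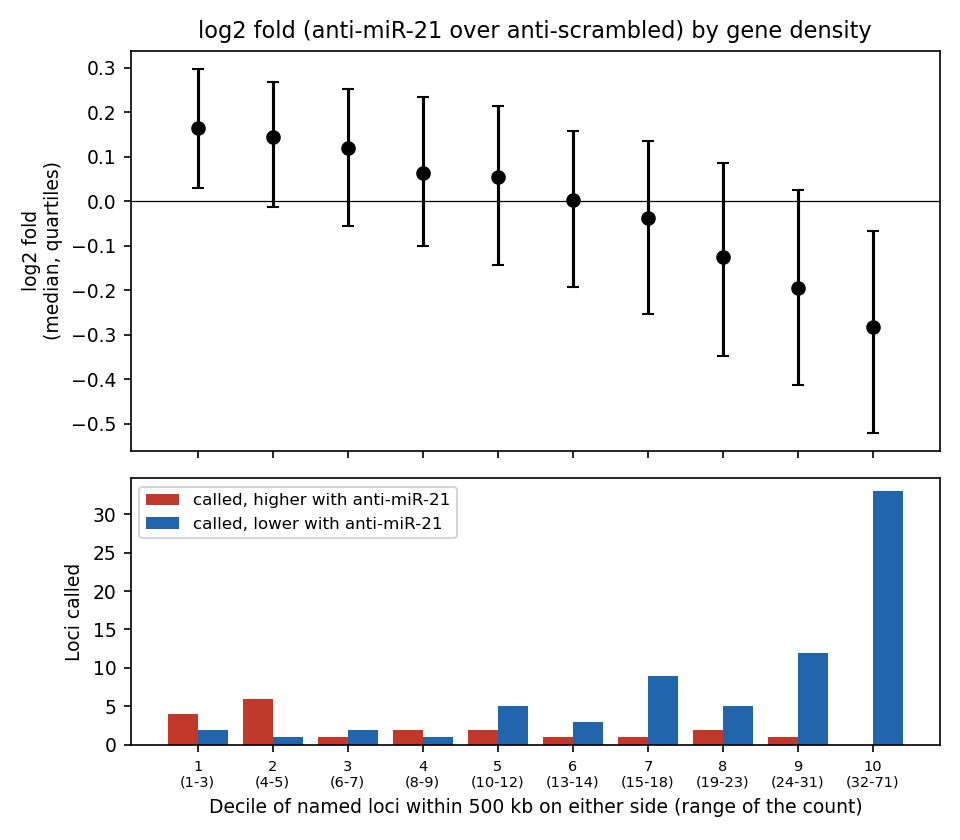
Named loci with a mean FPKM of at least 1 are grouped on the x axis into deciles of the number of named loci within 500 kb on either side. In the upper panel, dots are the median log2 fold of anti-miR-21 over anti-scr and bars span the quartiles, declining from 0.17 to -0.28; the lower panel counts loci called higher (red) and lower (blue) in the authors' deposited table, with 33 lower and 0 higher in the densest decile.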

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

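Random lists matched on gene density and the removal of density decile medians were chosen after the results were seen; the other alternatives were set before. No paired analysis was possible because the deposited table gives 1 value per group. For the same reason the limma fits with a pseudocount of 0.1, without a filter, with a replicate block and with each replicate left out were not run, and what any 1 pool contributes is open. The miR-21 seed site alternatives were not run because no 3' UTR sequence was used here. The count of called loci moved with the threshold. At q under 0.10 it was 169 (44 higher, 125 lower), and with an absolute log2 fold of at least 1 it was 41 (14 higher, 27 lower). At q under 0.01 it was 0, because the lowest deposited q is 0.0131. Many called loci share this q and the lowest deposited Cuffdiff p of 5e-05. The count of 0 was therefore fixed by that lowest p and does not grade the calls. With q recomputed at a mean FPKM of at least 1, 103 of the 105 called loci were kept. Recomputing q over all tested loci gave 105. Recentring by 0.01 and removing the density decile median do not alter the deposited q, and their shifts are smaller than any called fold, so they test neither the calls nor their direction. The miR-21 target median did not stand apart in the main setting. It did at a mean FPKM of at least 0.1 (0.15, percentile 99.7) and with the mean (0.11, percentile 99.41). It also did with log2 of FPKM + 1 (0.11, percentile 97.73), but so near the limit that the random draw can change its side. At a mean FPKM of at least 5 and with density-matched lists it did not. The cause of these differences was not tested. The fatty acid oxidation, PPAR-alpha, oxidative phosphorylation and extracellular matrix lists stood apart in the same direction under all 6 alternatives. For lists, however, recentring is not a test. It shifts a list and its random lists alike, so a percentile then changes only through the random draw. Over all 35 lists, the side of the threshold held for 29 at a mean FPKM of at least 5, 31 at 0.1 and 33 with FPKM + 1. It held for 31 with the mean and 31 with density-matched lists. After recentring it held for all 35, which was fixed in advance apart from the draw. The contractile list no longer stood apart with the mean (-0.15, percentile 4.69), and the cause was not tested. Adding 1 to both groups keeps the sign of every fold, so none of 93 named loci could change sign with FPKM + 1. Recentring can turn only folds between 0 and its shift of 0.01, which 3 of them had. Neither setting tests the direction of a named gene. The pools, 2 in each group, limit what the deposited test can resolve: the smallest called fold was 0.67 on the log2 scale, and no smaller fold of a single gene was called.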

Other observations

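Of the tests below, those on loci without a symbol, on locus length and on neighbouring genes were set before their results were seen, although the rule for picking the nearest loci was settled afterwards; the tests on list members, gene density, cell share, atrial genes and lung genes were chosen after the patterns they address had been seen.

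Atrial genes were higher with anti-miR-21 in these ventricular samples. Of 13 measured members of the atrial list, 12 were higher in value, with a median log2 fold of 0.33 above all of the random lists; Sln rose in the authors' deposited table, and 4 rose when adjusted over the list alone. Myl7 (210 and 335 FPKM, 0.68) and Myl4 (60.4 and 110 FPKM, 0.86), atrial myosin light chains chosen after their values were seen, were not called in the authors' deposited table. Bmp10, an atrial growth factor below the FPKM minimum and also chosen afterwards, had 0.106 and 1.38 FPKM and was called in the authors' deposited table. The 27 small noncoding loci with a fold stood apart (0.24, percentile 99.94; Mir98 -0.06, Mir22 0.24), but not at a mean FPKM of at least 5 (percentile 97.18) or with density-matched lists (percentile 91.52). Their values come from a total RNA library and not from mature small RNA, and none was called in the authors' deposited table or adjusted over the list alone. Lists of adipocyte (-0.19, percentile 9.82), neural and Schwann (0.04, percentile 56.95), mesothelial (0.17, percentile 81.35) and skeletal muscle genes (0.13, percentile 77.1) did not stand apart. They had no called member in the authors' deposited table. The most abundant adipocyte members were Gpd1 (-0.43, at a locus on chromosome X that can be a copy of the gene) and Acly (0.04). Those of the mesothelial list were Wt1 (-0.03) and Gpm6a (0.37), and those of the skeletal muscle list Casq1 (-0.41) and Myl1 (0.32). Adjusted over the list alone, 1 adipocyte gene and 1 neural and Schwann gene rose. At a mean FPKM of at least 5 the neural and Schwann list, with 2 genes left, stood apart (percentile 99.49).

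The decline of folds with gene density was not carried by the gene lists: rho was -0.44 over 9154 loci on no list. Nor did locus length account for it, since rho given locus length was -0.38. Each fold also followed the median of its 20 nearest named loci (rho 0.48 across genes, against at most 0.04 in 100 shuffles of the folds over positions). A difference between libraries that follows the genomic region, such as one in base composition, may underlie the trend; over 2982 loci without a symbol rho was -0.18, between the bounds of -0.2 and -0.1 set for and against it, so this and a response to the inhibitor cannot be told apart. Values per pool and base composition, which could separate them, were not analysed here.

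The lower metabolic lists were weighed against that trend. Among random lists matched on density and expression, the medians of fatty acid oxidation, oxidative phosphorylation, glycolysis and ribosomal protein genes lay at percentiles 0.00, 0.03, 0.02 and 0.06, which argues against density alone. After subtracting the median fold of the 20 nearest loci outside the list, percentiles were 0.03, 0.01 and 0.41 for the first 3 lists, but 12.5 for ribosomal proteins, whose lower values may be shared with their neighbourhood. A lower share of cardiomyocytes, with the other cells in unchanged proportions, would raise the markers of all other cells alike. Yet the macrophage median exceeded the endothelial one by 0.47, where random lists gave -0.20 to 0.20. This argues only against such an even change. A lower share of cardiomyocytes with more macrophages and fibroblasts but not more vessel cells stays open and untested. So do a response of cardiomyocyte metabolism to the inhibitor, a change in base composition bias per gene, and chance differences between pools.

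For the atrial genes, density-matched random lists put the median at percentile 99.99, which argues against the density trend. The 24 hypertrophy list members not on the atrial list had a median of -0.11 at percentile 7.57, but 14 were lower and the rest higher in value, so a hypertrophic programme stays open. Atrial tissue carried into an anti-miR-21 pool may explain the pattern. That 12 of 13 members were higher is the pattern itself. The same count would follow from a response to the inhibitor, so it cannot decide between them. Lung tissue is a further candidate source: Sftpc, the surfactant protein C gene, was listed at 0 with anti-scr and at 2.80 FPKM with anti-miR-21 and was called in the authors' deposited table, and 9 of 11 other lung genes were higher, among them Sftpa1 (0 and 0.725 FPKM) and Scgb1a1 (0 and 0.527 FPKM). Only 2 of the 11 reached an FPKM of 1 in a group, one of these, Ager, was lower (1.80 and 0.879 FPKM), and the list was written after several of its values had been seen, so the source remains open.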
